A study of Homo sapiens with 4 samples.

How the data were processed

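Expression was measured in 4 samples of the REH line, 2 untreated and 2 treated with L-asparaginase, each hybridised to 1 array of the same Agilent design with 1 dye. The deposited scanner tables hold, per spot, an intensity that the scanner software had already background-subtracted and spatially detrended, per the file headers, and that was not normalized between arrays. The deposited raw median intensity of each spot and of its local background, and the 0 or 1 flags for spots well above background, saturated or outlying, come from the same software, per the file headers. The headers name Feature Extraction 10.7.1.1 while the submitters' processing notes name version 9.1. The authors' deposited table of log2 values was set against the scanner values. Its treated minus untreated differences correlated with theirs at r = 1.00 over 42382 matched probes, with a median absolute difference of 0.03, so its scale is log2 and its direction that of signal. A correlation cannot show to which percentile its arrays were scaled. The median log2 change of the genes tested was −0.10 with that table and −0.07 here, so its scaling was close to the 75th percentile used here but not identical. Its column medians were −0.14 and −0.05 for the untreated and −0.07 and −0.07 for the treated arrays, and the baseline subtracted from each probe stays unknown.

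All 4 arrays lay on 1 slide with 1 scan, so slide and scan were not tested as batches. The groups occupied different rows of array positions on that slide, so position and group cannot be told apart. Nothing in the labels says whether replicates came from separate cultures, and p-values measure only the spread between these samples, which may be technical. Each array had 58717 spots for transcripts. The 75th percentile of the processed intensity was 1188 and 1136 on the untreated and 939 and 886 on the treated arrays, and outlier flags took 441, 407, 515 and 293 spots. Saturated spots numbered 0 on each array.

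Control spots and outlier spots were left out, log2 of the processed intensity was taken, each array's 75th percentile was subtracted and spots of 1 probe were averaged. Of 42405 probes, 24910 (58.7%) were named with 1 gene symbol by matching the accession in the deposited files, without its version, to a RefSeq gene table of assembly GRCh38.p14, and 17495 stayed unnamed. The files name build hg19, so no coordinates are given. Outlier flags removed 23 probes. A probe was tested if it was well above background on both arrays of at least 1 group (24499 probes), and the brightest tested probe represented its gene, which left 12951 named genes and 7416 unnamed transcripts, or 20367 tests. Of 3489 genes with more than 1 tested probe, 231 had probes that changed in opposite directions at an unadjusted p under 0.05. The design written before the data were examined assumed a gene name column and a mean signal column. The files used here have neither, so the accession match and the median signal took their place.

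Groups were compared with limma 3.58.1 (lmFit and eBayes, no trend, no block) in R 4.3.3 with the data.table package (version 1.17.8), and p-values were adjusted by Benjamini-Hochberg over all 20367 tests, two-sided, with a threshold of 0.05. A gene not well above background on either array of 1 group was given a bound, "at least N-fold", from the brighter group's mean against the mean, per array of the dimmer group, of the higher of the lowest signal well above background and the probe's own. Such a bound holds only under this background subtraction. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 28 lists, and again with an estimated correlation and with fry. With an estimated correlation camera takes its degrees of freedom from the arrays instead of the genes, so 4 arrays leave it little power. The lists, fixed before the data were examined, were the 16 described in the report, 8 others (endoplasmic reticulum chaperones, cytosolic ribosomal proteins, cholesterol synthesis, antioxidant response, replication-dependent histones, heat-shock proteins, interferon-stimulated genes, BCL2 family) and 4 of markers of other cell types (T-cell, myeloid, erythroid, fibroblast and epithelial). They held 844 entries, of which 763 were measured. Counts "adjusted over the list alone" apply Benjamini-Hochberg within the list.

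Genes named in the text were chosen by a rule fixed before the data were examined: the 6 highest and 6 lowest changes among called genes with a symbol that were well above background on all 4 arrays, ASNS, DDIT3, TRIB3, MYC, CDKN1A, MAP1LC3B and SQSTM1 whatever their values, the called member with the highest and with the lowest change of each list, all measured miR-634 targets and all called markers of other cell types, except for items that are not reported here. Other members named as examples were chosen after their values were seen. The members of the FOXO and glucocorticoid lists were fixed after the main comparison and before their own values were seen. The abundant myeloid list was fixed at the same stage, but most of its members were on lists already tested. LYZ, CD14, S100A8, S100A9 and FCN1 were on the myeloid marker list and CTSS on the lysosomal list, which leaves TYROBP and FCER1G.

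The alternatives planned were normexp background correction with an offset of 50 on the raw median signals, quantile normalization, scaling to the median, no filter on dim probes, a filter that required signal on all 4 arrays, the mean of a gene's probes, a variance trend, a replicate block, the authors' value table and leaving out each array in turn. Scaling to the 7 of 10 spike-in RNAs that were well above background on all 4 arrays was added after the data were seen. The test was checked on simulated data with 20367 genes and 2 arrays per group. It recovered 11.9% of 67 genes changed 1.5-fold, 49.3% of 67 changed 2-fold and 80.3% of 66 changed 4-fold, and called 2 of 20167 unchanged genes. In the data, by contrast, 12147 were called. With so few changed genes the Benjamini-Hochberg adjustment is stricter in the simulation, so these rates do not describe the power or false calls of this comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.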

Results

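Gene expression was measured in REH cells with and without L-asparaginase. REH is an established cell line from a B-cell precursor acute lymphoblastic leukaemia, and it carries the ETV6-RUNX1 fusion. L-asparaginase is an enzyme used to treat this leukaemia. It breaks down asparagine and, less efficiently, glutamine. The series held 2 untreated samples and 2 samples given L-asparaginase at 1 U/ml for 2 days, each on its own 1-colour Agilent array. Sample titles, source names and the series design all gave these groups, while a description field named transfection with a control microRNA or miR-634. The groups were taken from the titles, and reported miR-634 targets are described below for that reason. Of 58717 spots for transcripts on each array, 60.4% and 60.2% were well above background on the untreated arrays and 56.7% and 59.4% on the treated arrays. Across genes, the logged values of the untreated pair correlated at r = 0.998, those of the treated pair at r = 0.995 and those of arrays from different groups at r = 0.959 to 0.961 (genes are not independent replicates).

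The comparison of treated with untreated cells asks which transcripts L-asparaginase altered in REH cells. Targets of ATF4, the transcription factor of the amino acid stress response, were higher after treatment: 21 of 22 measured targets rose, with a median rise of 3.05-fold. Genes for ribosome biogenesis, mitosis, glycolysis and DNA replication were lower, with median log2 changes of −1.37, −1.11, −1.21 and −0.74. Each of these lists passed with the preset correlation. Each missed the threshold (adjusted p = 0.168) with an estimated correlation, a test that has little power with 2 arrays per group. ASNS, which encodes the enzyme that makes asparagine, rose 4.74-fold (log2 change 2.25 ± 0.06), and MYC, a transcription factor that drives growth genes, fell (log2 change −1.85 ± 0.06). Changes are treated minus untreated on the log2 scale after scaling each array to its 75th percentile. Errors are the standard errors of the limma fit with n = 2 arrays per group.

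Of 20367 genes and unnamed transcripts tested, 5633 rose and 6514 fell past an adjusted p of 0.05 (limma, Benjamini-Hochberg, two-sided). At least 2-fold changes were found for 1637 that rose and 1423 that fell, against 985 and 910 with normexp background correction, 1335 and 1878 with scaling to the median and 795 and 3969 with scaling to spike-in RNA. At least 8-fold changes were found for 103 that rose and 8 that fell. Among the 12951 with a gene symbol, 4097 rose and 4511 fell. For each of the 12147 calls, both treated arrays lay on one side of both untreated arrays. With 2 arrays per group the threshold nearly requires this, so it is no added evidence. The share of calls that rose was 46.4%, against 36.0% (4388 rose, 7809 fell) with scaling to the median and 16.9% (2516 rose, 12366 fell) with scaling to spike-in RNA, an alternative added after the data were seen. With normexp background correction it was 52.5% (6069 rose, 5485 fell). The scalings to the median and to spike-in RNA moved the median log2 change of all genes tested from −0.07 to −0.19 and −0.52, so the changes below are relative to the 75th percentile. Without untreated replicate 1, 8030 calls were made and 4158 of them fell, and without untreated replicate 2, 4114 fell.

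**Figure D1:**
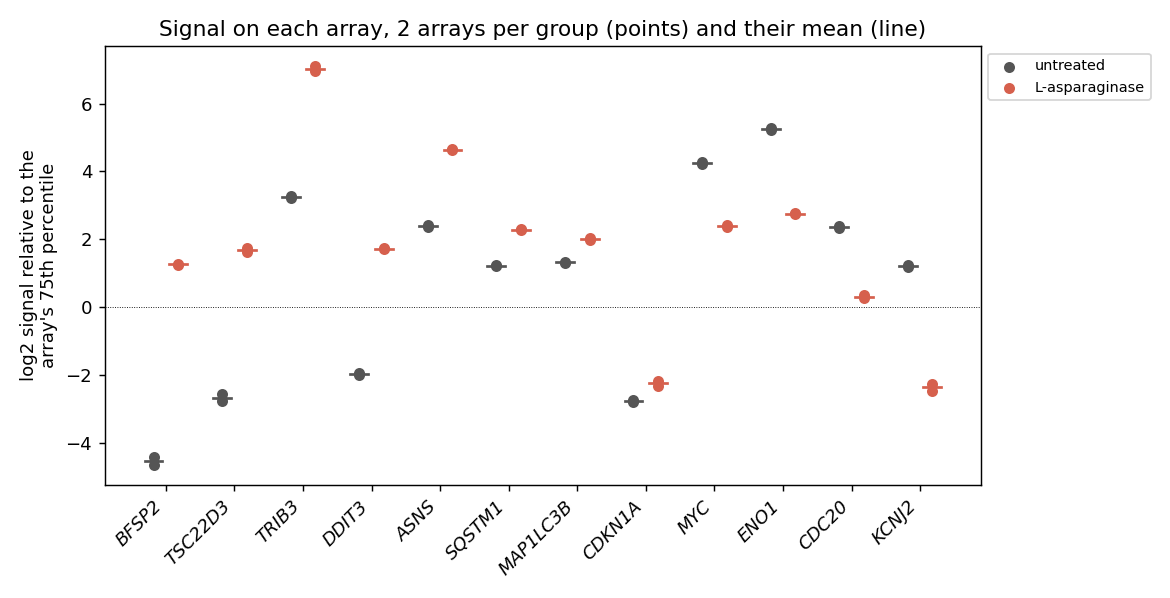
Log2 signal relative to the array's 75th percentile (vertical axis) for 12 named genes on the 2 untreated (grey) and 2 L-asparaginase (red) arrays, with 1 point per array and a line at the group mean. For each gene, as for every call, both treated points lie on one side of both untreated points, from a rise of 5.78 for BFSP2 to −3.57 for KCNJ2, and the rise of CDKN1A (0.51) shrinks to 0.07 with spike-in scaling.

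The largest rises among named genes well above background on all 4 arrays were those of BFSP2 (log2 change 5.78 ± 0.10, 55.1-fold), a lens filament protein gene, SPNS3 (5.27 ± 0.17) and MFAP4 (5.22 ± 0.06), which encodes an extracellular matrix protein. CYTL1, encoding a secreted cytokine-like protein, rose by 5.14 ± 0.07, TSC22D3, encoding the leucine zipper protein GILZ, by 4.35 ± 0.09 and GNAZ, encoding a G protein alpha subunit, by 4.25 ± 0.06. The lowest changes were those of KCNJ2, an inward rectifier potassium channel gene (−3.57 ± 0.09), FGFBP3 (−2.90 ± 0.07) and MFSD2A, which encodes a lysophospholipid transporter (−2.87 ± 0.06). NOL4 (−2.80 ± 0.13), the R-spondin receptor gene LGR5 (−2.77 ± 0.25) and FRG2C (−2.77 ± 0.11) followed. FRG2C belongs to a family of near-identical copies, and its probe could not be assigned to 1 copy with certainty. Of these genes LGR5 had the highest adjusted p (0.00227).

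ATF4 targets showed 21 rises and 0 falls among 22 measured members, also when adjusted over the list alone, and 16 rose at least 2-fold. camera, which compares a list with all other genes, gave an adjusted p of 2.29e-10, and the adjusted p = 0.168 with an estimated correlation. TRIB3, a pseudokinase gene induced under stress, rose 13.8-fold (3.79 ± 0.08) and DDIT3, which encodes the transcription factor CHOP, rose by 3.71 ± 0.06. DDIT4, ATF5 and CHAC1 rose by 3.31, 3.19 and 2.24. KDM7A was the 1 measured member not called (−0.11).

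Amino acid transporters went both ways. Of 16 measured, 7 rose and 3 fell (8 and 3 adjusted over the list alone), and the list had a median change of 0.16, which turned to −0.28 with spike-in scaling, and was not called (adjusted p = 0.0953). The glycine transporter gene SLC6A9 rose by 1.57 ± 0.09. SLC7A5, encoding the light chain of a large neutral amino acid transporter, rose by 1.18. The glutamate and aspartate transporter gene SLC1A3 was at least 3.76-fold lower after treatment, where it was not well above background.

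Enzymes that charge tRNAs, make serine or use asparagine and glutamine were also mixed. Of 22 cytosolic aminoacyl-tRNA synthetase genes and cofactors, 5 rose and 12 fell over all genes and adjusted over the list alone (median −0.28, camera adjusted p = 0.0964). The seryl-tRNA synthetase gene SARS1 rose by 1.00 ± 0.06 and the valyl-tRNA synthetase gene VARS1 changed by −2.10 ± 0.07. In serine and one-carbon metabolism 7 of 17 rose and 9 fell, with the same counts adjusted over the list alone. The median of that list was −0.40 and its mean 0.02, and it was not called (adjusted p = 0.731). The glycine cleavage gene AMT rose by 2.05 ± 0.09 and the folate enzyme gene MTHFD1 changed by −1.34 ± 0.06. Of 19 genes of asparagine, aspartate and glutamine metabolism, 4 rose and 12 fell (4 and 13 adjusted over the list alone), with a median of −0.40 and an adjusted p of 0.0745. Among the members that rose were ASS1, encoding argininosuccinate synthase (3.70 ± 0.08), ASNS and the aspartate aminotransferase gene GOT1 (0.30). The rise of GOT1 is smaller than the 0.443 that spike-in scaling subtracts, so it turns negative there, where 2 of the list rose and 14 fell. PPAT, which encodes the amidotransferase that starts purine synthesis, changed by −1.48 ± 0.05.

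Autophagy genes were higher relative to other genes, although with spike-in scaling 9 rose, 13 fell and the median turned from 0.27 to −0.17. Of 38 measured, 20 rose and 4 fell, also when adjusted over the list alone, and camera gave an adjusted p of 0.00101 (adjusted p = 0.168 with an estimated correlation). The autophagy receptor gene OPTN rose by 3.17 ± 0.07, and the receptor gene SQSTM1 rose 2.09-fold (1.06 ± 0.05). MAP1LC3B, which encodes the autophagosome protein LC3B, rose by 0.69 ± 0.06, and was 0.24 with spike-in scaling (adjusted p = 0.0574). WIPI1 and GABARAPL1 rose by 2.15 and 1.99. PIK3C3, the lipid kinase gene of autophagy initiation, changed by −1.24 ± 0.06.

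Lysosomal genes showed 22 rises and 5 falls among 36 measured, also when adjusted over the list alone, with a median of 0.46, whereas with spike-in scaling 9 rose, 12 fell and the median was 0.02. The camera adjusted p was 0.000474 (adjusted p = 0.168 with an estimated correlation). The cholesterol-binding protein gene NPC2 rose by 2.38 ± 0.05 and the acid ceramidase gene ASAH1 by 2.19. TFE3, a transcription factor of lysosomal genes, changed by −0.47 ± 0.08, while its other probe gave −0.05. The TFE3 call was lost with the mean of its probes (−0.26, adjusted p = 0.0556) and without untreated replicate 1 (adjusted p = 0.0608).

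Genes of energy metabolism fell together. In glycolysis 16 of 21 fell and 3 rose, 13 of them falling at least 2-fold, with an adjusted p of 0.000377 (adjusted p = 0.168 with an estimated correlation). The enolase gene ENO1 changed by −2.50 ± 0.06, LDHA by −2.07 and PKM by −1.93, while the lactate transporter gene SLC16A3 rose by 2.36 ± 0.10, ALDOC by 1.18 and PFKFB4 by 0.28. The rise of PFKFB4 is smaller than the 0.443 that spike-in scaling subtracts, so it turns negative there, where 2 glycolysis genes rose and 18 fell. In oxidative phosphorylation 56 of 67 fell and 2 rose (58 and 3 adjusted over the list alone), with a median of −0.61 and an adjusted p of 1.17e-09 (adjusted p = 0.255 with an estimated correlation). The cytochrome c gene CYCS changed by −2.22 ± 0.06, although its other probes ranged from −2.24 to −0.11. The members that rose were NDUFA10 (0.27 ± 0.05) and SDHA (0.25 ± 0.06), which had other probes as low as −0.03 and −0.21 and turned to −0.18 and −0.19 with spike-in scaling. Without untreated replicate 1 their adjusted p were 0.111 and 0.137, without untreated replicate 2 0.110 and 0.114. NDUFA10 also missed the threshold without L-asparaginase replicate 1 (0.0585) and SDHA without L-asparaginase replicate 2 (0.0687). In the tricarboxylic acid cycle 23 of 26 fell and 1, SDHA, rose, with a median of −0.69 and an adjusted p of 1.16e-05 (adjusted p = 0.168 with an estimated correlation). The fumarase gene FH changed by −1.40 ± 0.05. Adjusted over the list alone, the counts for glycolysis and the cycle were the same.

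Cell division genes fell almost throughout. In mitosis 38 of 39 fell, 26 of them at least 2-fold, with an adjusted p of 6.92e-12 (adjusted p = 0.168 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, changed by −2.05 ± 0.07, and the cyclin gene CCNA2 was 3.99-fold lower. BUB3 was the 1 member not called (0.07). In DNA replication 38 of 43 fell and 1 rose, with an adjusted p of 1.17e-09 (adjusted p = 0.168 with an estimated correlation). The origin licensing gene CDC6 changed by −1.68 ± 0.12, while CDT1, its partner in licensing, rose by 0.22 ± 0.06 (adjusted p = 0.0344) and was −0.22 with spike-in scaling. CDT1 missed the threshold with each array left out in turn, with adjusted p from 0.0630 to 0.179. Adjusted over the list alone, the counts of both lists were the same.

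Ribosome biogenesis had the lowest list median. Of 43 measured, 41 fell and 1 rose (42 and 1 adjusted over the list alone), 31 of them falling at least 2-fold, with an adjusted p of 6.09e-12 (adjusted p = 0.168 with an estimated correlation). RRP12, which acts in ribosomal subunit maturation, changed by −2.38 ± 0.09, and MYC, which is on this list, was 3.61-fold lower. POLR1D, a subunit gene of RNA polymerases I and III, rose by 0.41 ± 0.06, but its other probe gave −0.52, the change was −0.03 with spike-in scaling and the adjusted p was 0.0540 without untreated replicate 1.

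Targets of p53 were split. Of 30 measured, 15 rose and 7 fell, also when adjusted over the list alone, with a median of 0.13 that turned to −0.31 with spike-in scaling, where 3 rose and 16 fell. The list was not called (adjusted p = 0.220). TP53INP1, which encodes a stress-induced protein linked to autophagy, rose 4.77-fold (2.25 ± 0.09), the apoptosis gene BBC3 rose by 2.10, and the nuclease gene AEN changed by −1.71 ± 0.05. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.51 ± 0.08 (adjusted p = 0.00817). Its adjusted p was 0.0566 without untreated replicate 1, and its change was 0.07 with spike-in scaling (adjusted p = 0.602).

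B-cell precursor genes were higher relative to other genes. Of 36 measured, 23 rose and 5 fell, also when adjusted over the list alone, with a median of 0.47, which was 0.03 (13 rose, 10 fell) with spike-in scaling. The camera adjusted p was 0.000217 (adjusted p = 0.168 with an estimated correlation). CD72, a B-cell surface receptor gene, rose by 3.33 ± 0.07, VPREB3 by 1.97 and BACH2 by 1.67. CD38, which encodes a surface enzyme, changed by −1.20 ± 0.06.

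Among reported miR-634 targets, 2 of 6 measured rose and 4 fell, also when adjusted over the list alone, with a median of −0.44 and an adjusted p of 0.500. LAMP2, a lysosomal membrane protein gene, rose by 0.92 ± 0.05 and the caspase inhibitor gene XIAP by 0.46 ± 0.08 (0.01 with spike-in scaling, adjusted p = 0.898). The survivin gene BIRC5, which is also on the mitosis list, changed by −0.94 ± 0.06, OPA1, a mitochondrial fusion gene, by −0.73 ± 0.06, TFAM, the mitochondrial transcription factor gene, by −0.45 ± 0.10 and APIP by −0.44 ± 0.06. Without untreated replicate 1, XIAP, TFAM and APIP missed the threshold (adjusted p = 0.0799, 0.116 and 0.0519), and without untreated replicate 2, XIAP and TFAM did (0.0685 and 0.101).

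**Figure D2:**
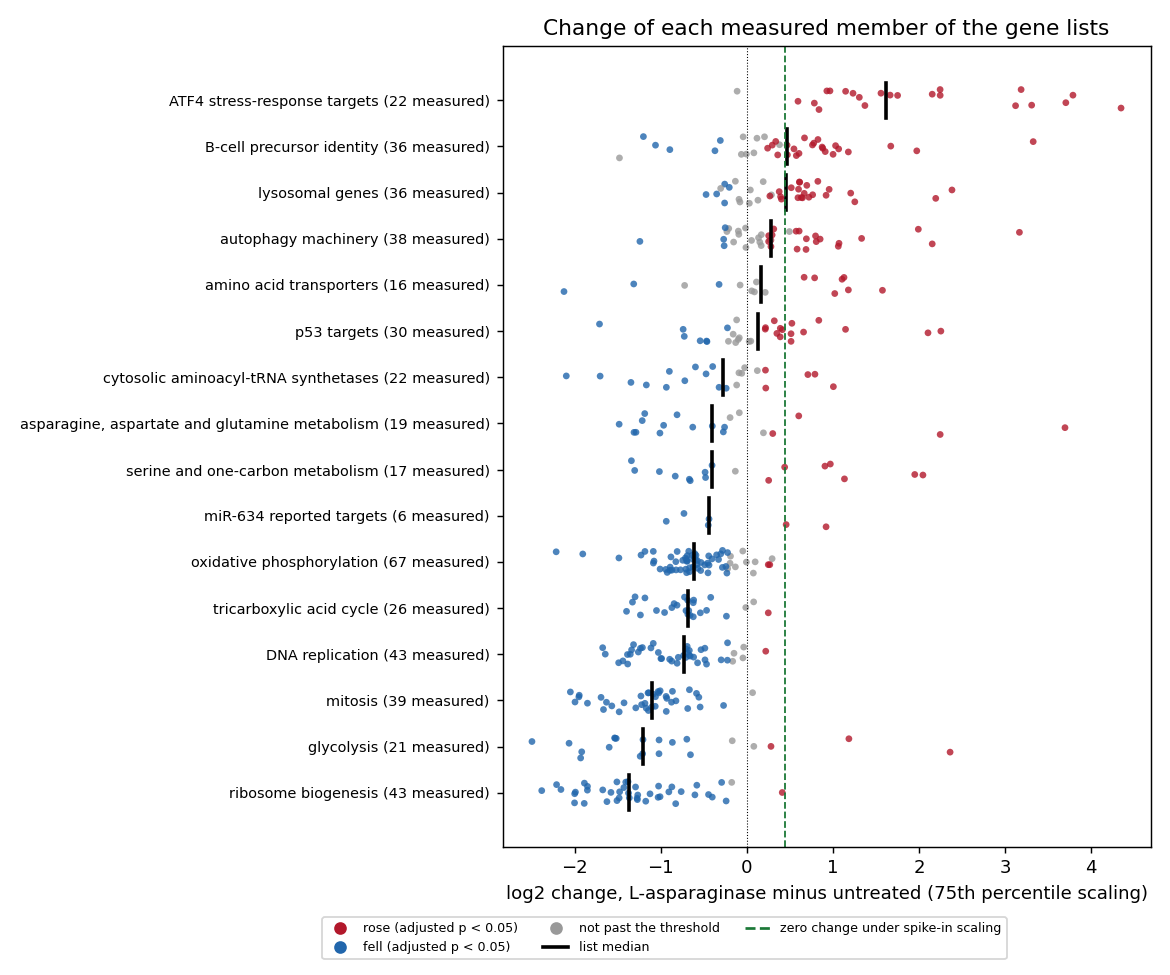
Log2 change, treated minus untreated, of each measured member of 16 gene lists, 1 point per gene, coloured by call, with a black bar at the list median and a dashed line where spike-in scaling puts 0. Medians ran from −1.37 for ribosome biogenesis to 1.61 for ATF4 targets, and those of autophagy genes, amino acid transporters and p53 targets lie left of the dashed line, so their direction flips with spike-in scaling.

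Of the 28 lists tested, 15 were past the threshold with camera's preset correlation, 0 with an estimated correlation and 25 with fry, which asks whether a list's genes move 1 way and does not compare them with other genes. The 0 does not show that correlation between genes made the calls. For mitosis the estimated correlation was 0.00873, below the preset 0.01, yet the unadjusted camera p went from 4.95e-13 to 0.0180. It was also below 0.01 for autophagy, lysosomal, glycolysis, tricarboxylic acid cycle, B-cell precursor, heat-shock and interferon-stimulated genes. For the other called lists it was higher, up to 0.117 for oxidative phosphorylation, 0.272 for histones and 0.277 for ribosomal proteins. For those lists the p-values with the preset may be too small. Estimating the correlation ties the test to the few degrees of freedom of these arrays. With 2 arrays per group the number of arrays limits the precision, and all p-values rest on the spread between these samples.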

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

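Both tests of the spike-in signal below, and scaling to spike-in RNA, were chosen only after the result was seen. The signal of the spike-in RNA, which the main comparison does not use, stood higher over the array's 75th percentile after treatment: by 0.443 on the log2 scale, or 1.36-fold, against a largest difference between replicates of 0.0839. Each of 7 spike-ins was higher on both treated arrays, by 0.22 to 0.52. The other 3 of 10 were left out because they were not well above background on all 4 arrays, and 1 of those went the other way (−0.44). Brighter scanning, labelling or hybridisation would move spike-ins and genes of the same intensity alike, but the unscaled change of a spike-in exceeded that of the 200 probes nearest in intensity by a median of 0.572 (0.155 to 0.727, above 0 for all 7), against 0.0562 between replicates, which argues against it. More spike-in mix per RNA input in the treated samples cannot be told apart from lower messenger RNA content of the treated cells' RNA: the unscaled spike-in signal changed by 0.0935 and the 75th percentile by −0.35, and array brightness is free to move both. Lower messenger RNA content per RNA input after L-asparaginase may be the source of the gap of 0.443, as a hypothesis. The amounts of mix and RNA added would be needed to test it, and other sources of the gap were not tested.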

How the results depend on the processing

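Scaling to spike-in RNA was the 1 alternative chosen only after the data were seen. Of 12147 calls, 11242 were kept with quantile normalization, 10893 with scaling to the median, 10576 with normexp and 9030 with spike-in scaling, where 42 were called in the opposite direction. With 1 array left out, 8030 to 11622 calls were made, 3872 to 5249 rose, 4114 to 6373 fell, 2968 to 3276 changed at least 2-fold and 13 to 15 lists passed. The 2 lowest counts of calls came without an untreated replicate (8030 and 8120). With 1 array left out, 0 of the calls changed sign. This was fixed in advance, since for each call both treated arrays lay on one side of both untreated arrays. Of 83 named genes, 18 lost the call in at least 1 of these fits, with adjusted p up to 0.179 for CDT1. Replicates share only a number: the deviations of same-numbered arrays correlated at r = 0.169 across genes, and the fit with the replicate block called 11966 (5502 rose, 6464 fell, 3084 at least 2-fold, 15 lists), of which 11266 were shared. No list changed its call under the block, and 2 named genes, CDT1 (adjusted p = 0.0680) and SLC4A1 (0.0591), did.

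The list count went from 15 to 0 with an estimated correlation, where so few arrays leave little power. It went to 25 with fry, which does not compare a list with other genes. The count of at least 2-fold changes, 3060, was 1895 with normexp, for a cause that was not tested, and 4764 with spike-in scaling. Over all calls, 2516 rose and 12366 fell with spike-in scaling. Spike-in scaling subtracts 0.443 from each change. Among the 83 genes named by the rule this reversed CDT1 (−0.22), EPOR (−0.10), ITGAM (−0.0605), NDUFA10 (−0.18), POLR1D (−0.0321) and SDHA (−0.19). It also reversed the medians of the BCL2 family (−0.15), amino acid transporters (−0.28), autophagy (−0.17), cholesterol synthesis (−0.38), ribosomal proteins (−0.33), myeloid markers (−0.0605) and p53 targets (−0.31). GOT1, PFKFB4 and ERRFI1, named as examples, rose by less than 0.443 and so reverse too. Scaling to the median reversed the medians of cholesterol synthesis (−0.0559) and ribosomal proteins (−0.00797), and the mean of a gene's probes reversed POLR1D (−0.0545). HBD was 0.0327 with normexp, and the median of fibroblast and epithelial markers was 0.0188 with normexp, 0.207 without a filter and, with 1 array left out, from −0.0832 to 0.0184 (the latter without untreated replicate 1). Calls were also lost by EBP (−0.15) and TFAM (−0.26) with quantile normalization, CSF1R, NDUFA10 and SLC4A1 with normexp, CDT1, EPOR, H2AC20, NDUFA10 and SDHA with scaling to the median, and NDUFA10, SDHA and TFE3 with the mean of a gene's probes. For these the cause was not tested. Apart from fry and the estimated correlation, the BCL2 family lost its list call under 5 settings (adjusted p up to 0.132) and ribosomal proteins under 10 (up to 0.369). Myeloid markers gained one under 6, asparagine, aspartate and glutamine metabolism (0.0256 and 0.0375) and aminoacyl-tRNA synthetases (0.0253 and 0.0184) with normexp and without a filter, and cholesterol synthesis with quantile normalization (0.0401). A filter on all 4 arrays gives no value for genes with only a bound. Slide as a block was not run, with 1 slide. Signal over background limits genes that were dim in 1 group to bounds.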

Other observations

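Predictions for the FOXO and glucocorticoid tests below were written before their results were seen. The myeloid prediction was written at the same stage, but its genes other than TYROBP and FCER1G were on lists already tested. Spike-in scaling was chosen after the data were seen. Genes of the BCL2 family and apoptosis were split: of 31 measured, 16 rose and 7 fell, also when adjusted over the list alone, with a median of 0.30 that turned to −0.15 with spike-in scaling (8 rose, 14 fell). The list's adjusted p was 0.0402, 0.0550 without untreated replicate 1 and 0.325 with an estimated correlation. BIK, a pro-apoptotic member not well above background in untreated cells, was at least 32.5-fold higher after treatment. BMF, HRK and BBC3, which encode other pro-apoptotic BH3-only proteins, rose by 3.15, 2.51 and 2.10, while BCL2, which opposes apoptosis, rose by 1.26. CYCS had the lowest change (−2.22). Interferon-stimulated genes showed 17 rises and 7 falls among 29, also when adjusted over the list alone, with a median of 0.44 and an adjusted p of 0.0105 (adjusted p = 0.219 with an estimated correlation), whereas with spike-in scaling 9 rose, 10 fell and the median was near 0 (0.0001). IRF7, a transcription factor of the interferon response, rose by 2.61 ± 0.06, and IFI44L was at least 2.61-fold lower, with an adjusted p of 0.0907 and 0.135 without untreated replicates 1 and 2.

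Heat-shock protein genes fell in 12 of 18 cases and rose in 2, with a median of −0.51 and an adjusted p of 0.00253 (adjusted p = 0.200 with an estimated correlation). The chaperone gene HSP90AB1 changed by −1.85 ± 0.06 and DNAJB4 rose by 0.74 ± 0.06. Of 23 endoplasmic reticulum chaperone genes, 6 rose and 13 fell (7 and 15 adjusted over the list alone), and the list was not called (median −0.38, adjusted p = 0.233). HERPUD1, a gene of protein degradation at that compartment, rose by 1.54 ± 0.06, EDEM1 by 1.18 and DNAJB9 by 1.14, while the chaperone genes HSP90B1 and HSPA5 changed by −1.07 ± 0.06 and −0.25. Of 33 histone genes of S phase, 29 fell and 1 rose, with a median of −0.70 and an adjusted p of 6.52e-07 (adjusted p = 0.325 with an estimated correlation). H1-5 changed by −1.75 ± 0.09 and H2AC20 rose by 0.57 ± 0.14, which missed the threshold without untreated replicate 2 (adjusted p = 0.0690) and without L-asparaginase replicates 1 and 2 (0.0960 and 0.0595), with scaling to the median (0.0591) and with spike-in scaling (0.13, adjusted p = 0.338). Histone genes have near-identical copies that can share probes. Antioxidant response genes numbered 3 rises and 11 falls among 20 (median −0.43, adjusted p = 0.0964). The pentose phosphate enzyme gene PGD changed by −1.44 ± 0.07 and the ferritin gene FTL rose by 0.74 ± 0.05. For heat-shock, histone and antioxidant genes the counts adjusted over the list alone were the same.

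Cytosolic ribosomal protein genes moved little, in contrast to ribosome biogenesis. Of 76 measured, 17 rose and 5 fell (0 and 1 adjusted over the list alone), the median was 0.11, which was −0.01 with scaling to the median and −0.33 (0 rose, 50 fell) with spike-in scaling, and the adjusted p of 0.0308 was 0.606 with an estimated correlation. It was 0.0574 and 0.0754 without untreated replicates 1 and 2 and 0.145 without L-asparaginase replicate 1. RPS3 rose by 0.46 ± 0.07 but missed the threshold without untreated replicates 1 and 2 (0.0580 and 0.0640), and was 0.02 with spike-in scaling. RPL27A changed by −2.37 ± 0.07. Both have many processed copies in the genome that can share probes. Of 23 cholesterol synthesis genes, 6 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of 0.06 that turned to −0.06 with scaling to the median and −0.38 with spike-in scaling (adjusted p = 0.431). INSIG1, a sterol sensor gene, rose by 1.23 ± 0.06 and EBP changed by −0.47 ± 0.06, or −0.15 (adjusted p = 0.139) with quantile normalization.

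Transcripts from lincRNA probes, which have no gene symbol here, showed 672 rises and 989 falls among 3683 (45.1% called, beside 66.5% of named genes, a difference that was not tested). Of lincRNA calls 40.5% rose, against 47.6% for named genes (Fisher's exact test, two-sided, p = 8.76e-08, with genes taken as independent). This split was made with the main scaling only. Over the alternatives the share of all calls that rose ran from 16.9% (spike-in scaling) to 52.5% (normexp).

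Of 8 measured T-cell markers, 1 rose (ZAP70, 1.26 ± 0.05) and 3 fell (adjusted p = 0.282): CD4 (−0.51 ± 0.11, missing the threshold without untreated replicate 1, at 0.0788, and without L-asparaginase replicate 2, at 0.0731), and GZMA and GZMK, at least 27.2-fold and 2.04-fold lower. Of 8 erythroid markers, 1 rose (EPOR, 0.34 ± 0.06, −0.10 with spike-in scaling) and 3 fell (1 and 2 adjusted over the list alone, adjusted p = 0.543), among them SLC4A1 (−0.38) and HBD, at least 1.26-fold lower. The log2 change of HBD was 0.0327 with normexp background correction, and its call was lost with a variance trend (adjusted p = 0.258). EPOR missed the threshold without untreated replicates 1 and 2 (0.0836 and 0.0882), HBD without untreated replicates 1 and 2 and L-asparaginase replicate 1 (0.0675, 0.135 and 0.0874) and SLC4A1 without untreated replicate 2 and L-asparaginase replicates 1 and 2 (0.126, 0.107 and 0.133). Of 4 fibroblast and epithelial markers 0 rose and 1, PDGFRB, fell (−0.57 ± 0.06, list adjusted p = 0.808). Counts for T-cell and for fibroblast and epithelial markers were the same adjusted over the list alone.

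Some myeloid markers rose, although the list was not called: of 9 measured, 5 rose and 1 fell, also when adjusted over the list alone, with a median of 0.38 (−0.06 with spike-in scaling) and a list adjusted p of 0.0669, or 0.0363 without untreated replicate 2 and 0.518 with an estimated correlation. MPO, encoding the granule enzyme myeloperoxidase, rose by 2.84 ± 0.06, CSF3R by 1.89 ± 0.06, CD33 by 1.67 ± 0.06, CD68 by 0.90 ± 0.14 and ITGAM by 0.38 ± 0.09 (adjusted p = 0.121, 0.0577 and 0.0809 without untreated replicates 1 and 2 and L-asparaginase replicate 2), while CSF1R was at least 1.82-fold lower, a call lost with normexp (−0.12, adjusted p = 0.265). Mature myeloid cells mixed into the treated cultures would bring their abundant transcripts, but of 7 such transcripts with a probe, 4 of them measured, 1 rose: CTSS (0.52), which the lysosomal list also holds. S100A8 and S100A9 were not well above background on any array, FCN1 was on 1 treated array, FCER1G fell (−0.998) and CD14, also on the marker list, and TYROBP gave −0.19 and −0.09, which argues against such a mixture. Apart from TYROBP and FCER1G, the abundant myeloid transcripts were on lists already tested, so their count was no independent test of a prediction. Immature myeloid cells may lack these transcripts, so the test cannot decide on them. A change of these markers within REH cells may remain, as a hypothesis (1 of 7 abundant myeloid transcripts rose, against mature myeloid cells mixed into the treated cultures), with immature myeloid cells and array position still open.

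TSC22D3 and TP53INP1, both among known targets of FOXO transcription factors, were among the larger rises. TSC22D3 is also a glucocorticoid target and had the highest change on the ATF4 target list (4.35), where 21 of 22 rose. Of 14 other measured FOXO targets, 10 rose (71.4%, exact 95% binomial interval 41.9% to 91.6%) and 2 fell, with a median of 1.06 and a camera p of 0.000863 (0.135 with an estimated correlation), and with spike-in scaling 8 rose and 4 fell. FBXO32 was at least 7.13-fold higher, YPEL3, PINK1 and TXNIP rose by 2.45, 1.42 and 1.36, and IL7R and BCL6 changed by −1.70 and −1.49. Of 10 other glucocorticoid targets, 3 rose (DUSP1 by 1.46, SGK1 by 0.76 and ERRFI1 by 0.42) and 4 fell, FKBP5 the most (−1.84), with a median of −0.05 and a camera p of 0.997, and with spike-in scaling 2 rose and 6 fell (median −0.49). The share and the median both met the bounds set beforehand against a glucocorticoid response (under 1 in 3 rising, or a median at or below 0). The share of 30% was close to the 31.6% of all named genes that rose. Its exact 95% binomial interval, 6.67% to 65.2%, reaches past its bound and the members went both ways, so a glucocorticoid response stays open. That interval was no part of the rule set beforehand, and none was required of the FOXO share. Raised FOXO activity is a candidate explanation for the TSC22D3 and TP53INP1 rises (10 FOXO targets rose), not separated from the ATF4 response, a glucocorticoid response or array position.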
